A study of Mus musculus with 23 samples.

How the data were processed

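The deposited table gives FPKM for 46077 genes in 23 libraries, and 1 misaligned line of it was left out. Per the submitters' processing notes, total RNA was prepared as libraries and sequenced by Novogene, reads were aligned with HISAT2 2.0.5, counted with featureCounts (version not given), and turned into FPKM by the authors. Strand use was not stated. The genome build is not given in the sources used here, and coordinates match GRCm38 as in GENCODE M21, where 99.9% of the 45228 shared identifiers overlap. Gene symbols stored as dates (27) were recovered by identifier.

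Each library's values are whole read counts divided by gene length and by 1 library size, since all of 457292 values checked lay within 0.00067 of a whole read. The size that the deposited FPKM use is 0.43 to 1.88 times the library's assigned reads, so the values already carry a scaling between libraries. Median-of-ratios factors computed on the deposited values were 0.9999 to 1.0001 over 14522 genes. Assigned reads ranged from 21.03 to 39.6 M (1e6 reads) per library. Mitochondrial reads, as percent of assigned reads, were 56.7, 55.3 and 65.0 in PNXM657, PNXM661 and PNXM649 (wild-type saline cardiomyocytes), 69.3, 80.0 and 78.5 in PNXM658, PNXM664 and PNXM663 (knockout saline), 78.1, 79.3, 75.6 and 75.8 in PNXM644, PNXM647, PNXM645 and PNXM648 (wild-type isoproterenol), and 46.8, 69.3, 59.5 and 68.8 in PNXM654, PNXM656, PNXM655 and PNXM646 (knockout isoproterenol). Headers reading WHO were taken as whole heart, since the series describes no other such tissue. The columns carry no replicate number, so no pairing or batch term was used. Libraries are taken as separate animals from their header identifiers, so that the p-values measure spread between libraries.

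Differences were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), among genes with an FPKM of at least 1 in as many libraries as the smallest group (3 for cardiomyocytes, 4 for whole hearts and for the comparison between tissues), with empirical Bayes moderation and a trend, two-sided, and Benjamini-Hochberg adjustment over all genes of a comparison. A gene is called at an adjusted p below 0.05. The 14 cardiomyocyte libraries were fitted together, as were the 9 whole-heart libraries, and the comparison between tissues used the isoproterenol libraries. The 26 gene lists were fixed before the data were examined. Each was tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and also with an estimated correlation and with fry. The preset correlation treats genes of a list as nearly independent. With it 101 of 179 list tests were called (54 higher and 47 lower), with the estimated correlation 1, and with fry 5. A list's result is the median log2 difference of its members that pass the filter. Members were also adjusted over their list alone.

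Per-library measures (32 in each comparison: 26 list scores, 2 differences of scores, Panx1, Panx2, assigned reads and mitochondrial percent) were tested by exact permutation of library labels, two-sided, within treatment or within tissue for the differences of effects, with Benjamini-Hochberg adjustment over the 32. Panx1 is named in every comparison, in whole hearts as FPKM alone because it lay below the filter there, and Myh6 between genotypes. Panx2, Panx3 and the controls Xist, Ddx3y and Kdm5d are given once, over groups or libraries. Beyond these, named genes are protein-coding genes with a mean of at least 1 FPKM in the higher group and a symbol that is not a placeholder. They are the 8 largest rises and 8 largest falls among called genes, or, where fewer than 8 genes are called, the 10 with the smallest unadjusted p. From each list up to 4 members with the smallest unadjusted p are named. Among falls in the wild-type response only 4 genes met these conditions, and 1 of them is not reported here.

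Alternatives were pseudocounts of 0.1 and 0.5, no filter, a filter of FPKM 5, robust moderation, array weights, protein-coding genes alone, median-of-ratios and quantile scaling, rescaling without mitochondrially encoded genes, fits of only the compared groups or of all libraries, and leaving out each library in turn. Chosen after the data were seen were voom on the recovered reads, FPKM without the scaling between libraries, covariates, and leaving out groups of libraries. In simulated counts with 100 genes changed at each fold, limma recovered 31, 54, 44 and 45% of 2-fold changes in the 4 cardiomyocyte comparisons and 89% in whole hearts, and 71, 82, 80, 83 and 100% of 4-fold changes. Simulated genes were independent, and the changed ones were drawn from genes with an FPKM of at least 2 in every library of the fit. These shares are therefore optimistic and do not cover lower-expressed genes that passed the filter. Mitochondrial pseudogenes in the nuclear genome can share reads with mitochondrial genes. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, with a random seed of 1.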

Results

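RNA sequencing was performed on 23 libraries from male mouse hearts. Cardiomyocytes isolated after dissociation gave 14 libraries, and 9 came from whole hearts. Wild-type mice carried a floxed Panx1 gene, which encodes pannexin 1, a membrane channel that releases ATP, and in knockout mice the gene was deleted with a driver from the Myh6 promoter, which is active in cardiomyocytes. Mice received saline or isoproterenol, a beta-adrenergic agonist, at 15 mg/kg/day for 14 days. Cardiomyocytes were sampled from wild-type (n = 3) and knockout (n = 3) mice after saline and from wild-type (n = 4) and knockout (n = 4) mice after isoproterenol. Whole hearts came from mice labelled wild-type (n = 5) and knockout (n = 4) after isoproterenol. The series title names cardiomyocyte metabolism and neutrophil recruitment in non-ischemic heart failure as its subject.

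Reads assigned to genes are given in M (1e6 reads). They numbered 30.1, 29.9 and 25.7 M in wild-type saline cardiomyocytes, 24.1, 24.3 and 24.1 M in knockout saline cardiomyocytes, 23.1, 24.9, 24.1 and 21.03 M in wild-type isoproterenol cardiomyocytes, and 31.9, 25.9, 24.8 and 24.4 M in knockout isoproterenol cardiomyocytes. Whole hearts had 32.7, 35.3, 30.0 and 39.6 M when labelled knockout and 32.9, 34.4, 29.8, 28.9 and 38.7 M when labelled wild-type. Much of the cardiomyocyte sequence came from the mitochondrial chromosome, so that reads from other chromosomes averaged 11.8 and 5.80 M after saline and 5.30 and 10.6 M after isoproterenol, in wild-type and knockout cells in that order. All changes are differences of log2(FPKM + 1), where FPKM is fragments per kilobase and M reads, with their standard error from limma, and they are relative to the scaling between libraries that the deposited values carry. Without that scaling, the median of all genes shifted by -0.70 in the saline knockout comparison, 0.56 in the isoproterenol knockout comparison, -0.82 and 0.44 in the wild-type and knockout isoproterenol responses, 1.29 in their difference, 0.13 in whole hearts and -0.41 between the tissues. With totals set equal over genes outside the mitochondrial chromosome, the median shifted by -0.16 in the saline knockout comparison, -0.27 in the wild-type response and 0.25 in the difference of the responses.

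Panx1 (chromosome 9, 15005161 to 15045478) was measured first in every group, because it checks the labels. In saline cardiomyocytes it was 1.67 ± 0.36 FPKM (SD, n = 3) in knockout and 2.21 ± 0.66 FPKM (SD, n = 3) in wild-type cells (exact permutation p = 0.3, two-sided), and with 3 against 3 libraries no p below 0.1 is possible. After isoproterenol it was 1.04 ± 0.12 FPKM (SD, n = 4) in knockout and 1.55 ± 0.28 FPKM (SD, n = 4) in wild-type cells, lower in all 4 knockout libraries than in any wild-type library (exact permutation p = 0.0286, adjusted p = 0.229 over 32 measures). Whole hearts went against their labels, with 0.651 ± 0.189 FPKM (SD, n = 4) in hearts labelled knockout and 0.412 ± 0.066 FPKM (SD, n = 5) in hearts labelled wild-type. All 4 hearts labelled knockout lay above the wild-type mean (exact permutation p = 0.0159, adjusted p = 0.169). The groups overlapped, with 0.469 FPKM in PNXM242, labelled knockout, and 0.512 FPKM in PNXM240, labelled wild-type. A gene-level value also counts reads outside the deleted part and reads from cells other than cardiomyocytes. Panx2 averaged between 0.0818 and 0.709 FPKM per group, and Panx3, a skeletal pannexin, did not exceed 0.0386 FPKM in any library. Xist, transcribed in female cells, did not exceed 0.0179 FPKM in any library, whereas the Y-linked Ddx3y and Kdm5d were at least 3.12 and 0.260 FPKM in every library.

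**Figure D1:**
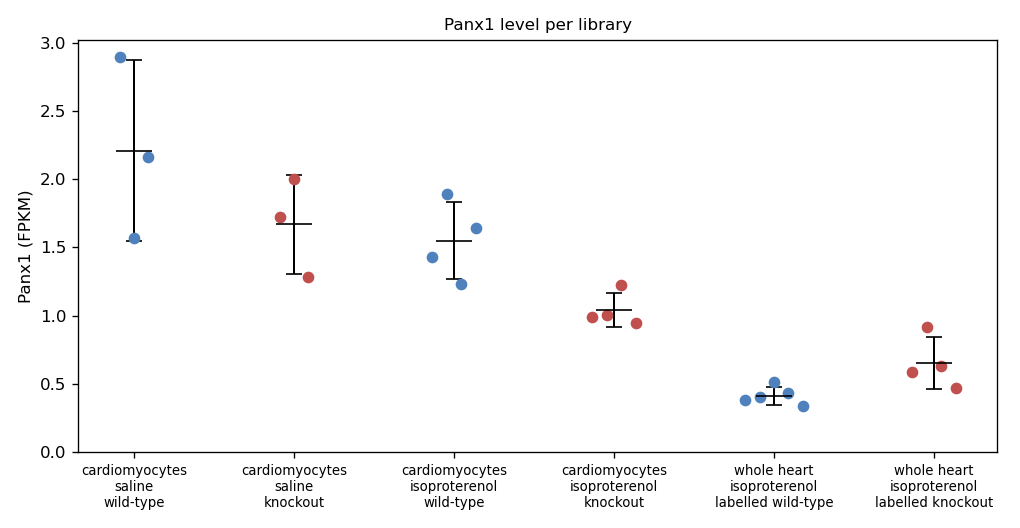
Panx1 FPKM on the vertical axis for each library (points) with group mean and SD in the 6 groups. Knockout cardiomyocytes averaged 1.67 FPKM after saline and 1.04 FPKM after isoproterenol, below 2.21 and 1.55 FPKM in wild-type cells, whereas hearts labelled knockout averaged 0.651 FPKM, above the 0.412 FPKM of hearts labelled wild-type.

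The first comparison asked what loss of Panx1 does in cardiomyocytes of saline-treated mice. Transcripts of the mitochondrial genome were more abundant in knockout cells: mt-Atp6 (mitochondrial chromosome, 7927 to 8607), a subunit of ATP synthase, was 36600 ± 15100 FPKM (SD, n = 3) against 11100 ± 4200 FPKM (SD, n = 3). The mt-Atp6 difference was 1.70 ± 0.37. The cytochrome c oxidase subunits mt-Co3, mt-Co2 and mt-Co1 differed by 1.67 ± 0.39, 1.64 ± 0.43 and 1.37 ± 0.37, and the complex I subunits mt-Nd1 and mt-Nd2 by 1.37 ± 0.35 and 1.33 ± 0.36. Mitochondrial reads made up 75.9 ± 5.8% (SD, n = 3) of assigned reads in knockout and 59.0 ± 5.2% (SD, n = 3) in wild-type cells. Every knockout library lay above every wild-type library (exact permutation p = 0.1, the smallest that 3 against 3 libraries allow; adjusted p = 0.246). Of the other genes with the smallest p-values, Ramp2 (0.80 ± 0.21), a subunit of adrenomedullin receptors, Scarf1 (0.57 ± 0.16), an endothelial scavenger receptor, and Gadd45g (0.79 ± 0.22), a stress-inducible gene, were higher. Celsr1 (-0.55 ± 0.15, and -1.12 with a pseudocount of 0.1), a planar polarity cadherin, was lower. None of these passed limma's test, which called 0 of 11919 genes (421 at an unadjusted p under 0.05; voom called 0). Panx1 itself differed by -0.25 ± 0.17, a value of -0.10 without library PNXM657, -0.40 without PNXM661 and -0.15 without PNXM663. Without PNXM657 10 genes were called and without PNXM649 1.

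In the fixed gene lists of the same saline comparison, all 13 mitochondrially encoded proteins were higher in knockout cells (median 1.34, camera adjusted p = 1.11e-17, and adjusted p = 0.183 with an estimated correlation), 11 of them when adjusted over the list alone and 0 over all genes. Quantile normalisation put this median at 0.00, because most of these genes hold the top ranks in every library and equal ranks receive equal values. Nuclear genes of the same organelle were higher too. All 40 respiratory chain genes (median 0.77, adjusted p = 2.13e-10, and adjusted p = 0.552 with an estimated correlation), such as Ndufa2 (1.04 ± 0.51), all 24 genes of the tricarboxylic acid cycle (0.59, adjusted p = 1.48e-06, and adjusted p = 0.552 with an estimated correlation), such as Dlat (0.60 ± 0.32), were higher. The same held for 28 of 30 genes of fatty acid oxidation (0.56, adjusted p = 2.00e-06, and adjusted p = 0.552 with an estimated correlation), such as the fatty acid transporter Cd36 (0.52 ± 0.26), and for 20 of 21 genes of contraction and calcium handling (0.82, adjusted p = 3.37e-07, and adjusted p = 0.552 with an estimated correlation), among them triadin, Trdn (0.92 ± 0.32), and cardiac troponin T, Tnnt2 (1.18 ± 0.44). Myh6, the adult alpha-myosin heavy chain (chromosome 14, 54941981 to 54966927), differed by 0.89 ± 0.48, and by 0.57 without PNXM657. In the hypertrophy and fetal programme 12 of 14 genes were higher (0.49, adjusted p = 2.27e-05, and adjusted p = 0.286 with an estimated correlation; 0.23 without PNXM657). The fetal myosin Myh7 (1.18 ± 0.37) and the matricellular gene Ctgf (0.97 ± 0.29) passed 0.05 when adjusted over the list alone. Members with the next smallest p were Acta1 (1.64 ± 0.59) and Ankrd1 (1.19 ± 0.43).

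Markers of other cells also differed in saline knockout preparations. All 14 fibroblast markers were higher (median 0.45, adjusted p = 2.27e-05, and 0.552 as adjusted p with an estimated correlation), with Gsn at 0.80 ± 0.30 and Tcf21 at 0.53 ± 0.24. The fibroblast median was 0.20 without PNXM657, 0.68 without PNXM658 and 0.27 without PNXM664, and under quantile normalisation the call was lost at 0.28. Of 14 endothelial markers 13 were higher (0.40, adjusted p = 3.48e-05, and adjusted p = 0.454 with an estimated correlation; 0.23 and not called under quantile normalisation), among them Vwf (0.91 ± 0.29), Eng (0.73 ± 0.25) and Emcn (0.53 ± 0.21). Smooth muscle and pericyte markers were higher in 8 of 9 (0.36, adjusted p = 0.00442, and adjusted p = 0.305 with an estimated correlation), a call lost without PNXM658 (0.18) or PNXM649 (0.28). Genes induced by dissociation and heat shock were lower in 14 of 17 (median -0.48, adjusted p = 1.88e-05, and adjusted p = 0.138 with an estimated correlation; -0.23 without PNXM649). Socs3 was at -0.78 ± 0.24, the early response gene Egr1 at -0.70 ± 0.24 (-0.38 without PNXM661) and the chaperone gene Hspa1b at -0.76 ± 0.25 (-0.38 without PNXM657). Proliferation genes were lower in 12 of 12 (-0.53, adjusted p = 0.00306, and adjusted p = 0.668 with an estimated correlation). Their median was -0.97 with a pseudocount of 0.1, 0.05 without PNXM657, -0.85 without PNXM661, -1.09 without PNXM658, -0.34 and not called without PNXM664 and -0.09 and not called without PNXM663. Neutrophil markers were lower in 15 of 16 (-0.59, adjusted p = 0.0375, and adjusted p = 0.693 with an estimated correlation), with the call lost under quantile normalisation (-0.62) and without PNXM661 (-0.78), PNXM658 (-0.43) or PNXM649 (-0.08). Macrophage markers were lower in 17 of 18 (-0.22, adjusted p = 0.0108, and adjusted p = 0.693 with an estimated correlation; -0.33 under quantile normalisation, -0.57 without PNXM657 and -0.46 without PNXM664), a call lost without PNXM661 (-0.29), PNXM658 (-0.09), PNXM649 (0.12) or PNXM663 (-0.12). Lymphocyte markers did not pass (-0.49, adjusted p = 0.0634, 13 of 14 lower; 0.45 without PNXM657 and -0.12 without PNXM663). They were called with a pseudocount of 0.1 (-0.56) and without PNXM661 (-0.86), PNXM658 (-0.78), PNXM664 (-0.37) or PNXM649 (-0.62). Pannexins, connexins and purinergic receptors as a list did not pass (0.09, adjusted p = 0.107, 8 of 13 higher; -0.0138 without PNXM664).

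The second comparison asked the same of mice given isoproterenol, and here mitochondrially encoded transcripts were lower in knockout cells. mt-Atp8 was 313 ± 35.1 FPKM (SD, n = 4) against 747 ± 168 FPKM (SD, n = 4), a difference of -1.23 ± 0.29, mt-Nd2 differed by -1.22 ± 0.31 and mt-Co1 by -1.24 ± 0.32. All 13 were lower (median -1.23, adjusted p = 1.51e-15, and adjusted p = 0.396 with an estimated correlation; 0.00 under quantile normalisation, which equalises values at the top ranks), 12 when adjusted over the list alone and 0 over all genes. Mitochondrial reads made up 61.1 ± 10.6% (SD, n = 4) in knockout and 77.2 ± 1.8% (SD, n = 4) in wild-type cells, lower in all 4 knockout libraries than in any wild-type library (exact permutation p = 0.0286, adjusted p = 0.229). In the hypertrophy programme 10 of 14 genes were higher (median 0.36, adjusted p = 0.000138, and adjusted p = 0.402 with an estimated correlation; 0.21 without PNXM654). Ctgf was 19.98 ± 2.94 FPKM (SD, n = 4) against 9.38 ± 1.40 FPKM (SD, n = 4), a difference of 1.01 ± 0.25, Ankrd1 differed by 1.43 ± 0.37, and Nppb, which encodes B-type natriuretic peptide, by 2.20 ± 0.70. These 3 passed when adjusted over the list alone and not over all genes. Limma called 0 of 11919 genes (739 at an unadjusted p under 0.05; voom called 0). Among the smallest p-values, the myelin and lymphocyte gene Mal was higher (0.76 ± 0.19), and Rbp7, a retinol-binding protein (-1.05 ± 0.26), the kinase Ptk2b (-0.99 ± 0.24) and the immunoproteasome subunit Psmb9 (-0.58 ± 0.14) were lower. Lower values were also seen for Aldh18a1, an enzyme of proline synthesis (-0.45 ± 0.11), the small GTPase Rac3 (-0.55 ± 0.13, and -0.91 with a pseudocount of 0.1), Fam117a (-1.03 ± 0.26) and Clic3 (-1.42 ± 0.36). Panx1 differed by -0.32 ± 0.14, and by -0.52 with a pseudocount of 0.1. Myh6 differed by 0.48 ± 0.41, and by 0.31, 0.25, 0.31, 0.78 and 0.73 without PNXM644, PNXM654, PNXM647, PNXM656 and PNXM648.

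Nuclear genes of energy metabolism went the other way from the mitochondrially encoded ones after isoproterenol. Fatty acid oxidation genes were higher in 29 of 30 (median 0.48, adjusted p = 5.12e-07, and adjusted p = 0.402 with an estimated correlation), with Ucp3 at 1.10 ± 0.35 and Pdk4, an inhibitor of pyruvate dehydrogenase, at 1.07 ± 0.32. The tricarboxylic acid cycle and pyruvate entry list was higher in 24 of 24 (0.48, adjusted p = 4.99e-07, and adjusted p = 0.402 with an estimated correlation). Its pyruvate carrier Mpc1 was at 0.93 ± 0.36 (0.59 without PNXM654). Nuclear respiratory chain genes were higher in 40 of 40 (0.44, adjusted p = 4.66e-06, and adjusted p = 0.498 with an estimated correlation). Contraction genes were higher in 19 of 21 (0.55, adjusted p = 7.56e-06, and adjusted p = 0.402 with an estimated correlation), with Sorbs2 at 0.59 ± 0.27. Per-library scores (mean log2(FPKM + 1) over a list) overlapped between the genotypes in each of these lists. The respiratory chain score was 5.59 to 7.85 in knockout and 5.90 to 7.35 in wild-type libraries. Single libraries moved the medians of these lists. Without PNXM654 they were 0.21, 0.19, 0.08 (no longer called) and 0.25 in the order given, without PNXM656 0.76, 0.79, 0.79 and 0.95, and without PNXM648 0.73, 0.75, 0.75 and 0.90. Without PNXM647 the first 3 were 0.30, 0.31 and 0.28, and without PNXM655 the respiratory chain median was 0.25. The 16 genes of beta-adrenergic and cAMP signalling did not pass (0.05, adjusted p = 0.220, 0.12 without PNXM648). Atrial markers did not pass either (-0.77, adjusted p = 0.0535, 6 of 7 lower, -0.50 without PNXM647), although they were called under quantile normalisation (-0.67) and without PNXM656 (-0.94), PNXM646 (-0.78) or PNXM648 (-0.77).

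Immune and blood transcripts were lower in the same knockout preparations. All 16 neutrophil markers were lower (median -1.36, adjusted p = 1.05e-05, and adjusted p = 0.402 with an estimated correlation), although the median was -0.88, -0.53, -2.26 and -0.79 without PNXM654, PNXM647, PNXM645 and PNXM648. Of the signals and adhesion molecules that recruit neutrophils, 12 of 14 were lower (-0.27, adjusted p = 0.00499, and adjusted p = 0.402 with an estimated correlation), with the chemokine Ccl5 at 1.73 ± 1.03 against 4.22 ± 0.38 FPKM (SD, n = 4 each). That Ccl5 difference of -1.01 ± 0.28 passed when adjusted over the list alone, and complement C3 was at -1.12 ± 0.51. This recruitment call was lost without PNXM654 (-0.18), and the median was -0.12 without PNXM647 and -0.42 with a pseudocount of 0.1. All 14 lymphocyte markers were lower (-0.87, adjusted p = 4.80e-05, and adjusted p = 0.396 with an estimated correlation; -1.37 with a pseudocount of 0.1), including the B cell receptor genes Cd79a (-1.46 ± 0.54) and Cd79b (-1.32 ± 0.51) and the cytotoxic granule gene Nkg7 (-0.89 ± 0.30). Macrophage markers were lower in 16 of 18 (-0.25, adjusted p = 0.0209, and adjusted p = 0.557 with an estimated correlation), a call lost without PNXM654 (-0.15), PNXM647 (-0.11) or PNXM645 (-0.26). All 9 erythroid transcripts were lower (-1.43, adjusted p = 1.08e-05, and adjusted p = 0.402 with an estimated correlation; -2.18 without PNXM645), with Bpgm at -1.43 ± 0.67. All 14 fibroblast markers were lower too (-0.35, adjusted p = 6.18e-05, and adjusted p = 0.402 with an estimated correlation; -0.21 without PNXM654), with Tcf21 at -0.54 ± 0.20 and Fbln1 at -0.85 ± 0.34. The integrated stress response was lower in 13 of 17 (-0.26, adjusted p = 0.000591, and adjusted p = 0.402 with an estimated correlation; -0.16 without PNXM647), with Trib3 (-0.49 ± 0.13) passing when adjusted over the list alone and the serine synthesis enzyme Phgdh at -1.01 ± 0.38. Interferon response genes were lower in 14 of 17 (-0.23, adjusted p = 0.00263, and adjusted p = 0.402 with an estimated correlation), with Gbp2 at -0.63 ± 0.27. Their call was lost without PNXM654 (-0.06), with -0.35 and -0.13 without PNXM656 and PNXM655. Smooth muscle and pericyte markers were called higher (0.33), a call lost without PNXM645 (0.34), PNXM656 (0.27), PNXM655 (0.27) or PNXM648 (0.31). Proliferation genes were called lower (-0.39), a call lost without PNXM654 (-0.31), PNXM647 (-0.16), PNXM655 (-0.37) or PNXM648 (-0.33). With an estimated correlation 0 lists were called in this comparison.

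The third comparison asked how wild-type cardiomyocytes respond to isoproterenol. Limma called 84 of 11919 genes, 78 higher and 6 lower, and in all 84 the groups did not overlap, as in 18.8% of all genes tested where chance gives 5.71%. Rbp7 (chromosome 4, 149449687 to 149454978) rose by 2.08 ± 0.28, from 11 ± 1.81 FPKM (SD, n = 3) to 50.3 ± 12.1 FPKM (SD, n = 4) (limma adjusted p = 0.0182). The tissue inhibitor of metalloproteinases Timp4 rose by 1.80 ± 0.37, and mitochondrially encoded mt-Co3, mt-Atp6, mt-Co2, mt-Atp8, mt-Nd1 and mt-Nd2 rose by 2.01, 1.95, 1.93, 1.82, 1.71 and 1.67. The endothelial receptors Eng and Tie1 rose by 1.19 ± 0.23 and 0.99 ± 0.21, and Trib3, a pseudokinase of the stress response, by 1.05 ± 0.14. Itga4, the leukocyte integrin alpha 4, fell by 1.16 ± 0.24, Sesn3 by 0.89 ± 0.16 and the ubiquitin ligase gene Herc4 by 0.73 ± 0.15. With a pseudocount of 0.1, mt-Co2, mt-Nd1, mt-Nd2 and Itga4 (-1.87) were not called (adjusted p = 0.0624, 0.0707, 0.0724 and 0.0902). Of the 84 genes 73 were protein-coding, some of them on the mitochondrial chromosome, where 11 of the 84 lay. The count rested on single libraries: 0 genes were called without PNXM661, PNXM644, PNXM647 or PNXM648 (voom called 98 with all libraries, 76 of them shared, and limma had 2896 genes at an unadjusted p under 0.05), 18 without PNXM657 (4 higher and 14 lower), 88 without PNXM649 and 222 without PNXM645. Of the genes named here, Rbp7 and Trib3 kept their call without PNXM657, and Timp4, Itga4, Herc4, Eng and Tie1 lost theirs without PNXM649. With only the compared groups in the fit 2 genes were called, 0 higher and 2 lower, with 1 shared, and under quantile normalisation 2, both higher. The split between higher and lower also moved, to 58 and 49 without a filter, 547 and 542 with all libraries in 1 fit, and 773 and 489 with array weights. Without the scaling between libraries 14 genes were called higher and 7550 lower, and with totals set equal outside the mitochondrial chromosome 0 were called. Panx1 differed by -0.32 ± 0.16, and by -0.17 without PNXM657.

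Lists in the wild-type response followed these genes. All 13 mitochondrially encoded proteins were higher (median 1.67, adjusted p = 1.51e-10, and adjusted p = 0.528 with an estimated correlation; 0.00 under quantile normalisation, which equalises values at the top ranks), 7 over all genes and 12 when adjusted over the list alone. All 14 endothelial markers were higher (0.78, adjusted p = 1.45e-06, and adjusted p = 0.528 with an estimated correlation; 0.35 and not called under quantile normalisation), 2 over all genes and 9 when adjusted over the list alone. Egfl7 (0.86 ± 0.20) and Emcn (0.74 ± 0.20) were among the 9, and Egfl7 was called over all genes without PNXM645 (0.93). Nuclear respiratory chain genes were higher in 40 of 40 (1.07, adjusted p = 3.92e-09, and adjusted p = 0.662 with an estimated correlation; 0.56 under quantile normalisation), with Uqcrq at 1.76 ± 0.59 and Ndufa2 at 1.45 ± 0.48. Contraction genes were higher in 20 of 21 (0.84, adjusted p = 0.000581, and adjusted p = 0.662 with an estimated correlation; 0.40 under quantile normalisation and 0.52 without PNXM648), with Trdn (1.19 ± 0.30) and the myosin light chain gene Myl2 (1.85 ± 0.54) past 0.05 when adjusted over the list alone. Fatty acid oxidation was higher in 27 of 30 (0.57, adjusted p = 0.00122, and adjusted p = 0.662 with an estimated correlation; 0.31 under quantile normalisation and 0.35 without PNXM648), with Etfb at 1.52 ± 0.51 and Cd36 at 0.71 ± 0.24. The tricarboxylic acid cycle was higher in 24 of 24 (0.65, adjusted p = 0.000886, and adjusted p = 0.662 with an estimated correlation; 0.41 without PNXM648, and 0.21 and not called under quantile normalisation). Glycolysis was higher in 20 of 23 (0.37, adjusted p = 0.0154, and adjusted p = 0.662 with an estimated correlation; 0.56 without PNXM649), with muscle phosphoglycerate mutase Pgam2 at 1.63 ± 0.52, and its call was lost under quantile normalisation (0.19) and without PNXM648 (0.34). Ribosomal protein genes were higher in 35 of 35 (0.54, adjusted p = 1.45e-06, and adjusted p = 0.662 with an estimated correlation; 0.35 without PNXM661), with Rps19 at 0.72 ± 0.25, but turned to -0.11 under quantile normalisation.

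Other cell types differed in the wild-type response too. Fibroblast markers were higher in 12 of 14 (median 0.45, adjusted p = 0.00625, and adjusted p = 0.662 with an estimated correlation), with Tcf21 (0.86 ± 0.22), Gsn (1.05 ± 0.28) and Col6a2 (0.65 ± 0.21) past 0.05 when adjusted over the list alone. This fibroblast call was lost under quantile normalisation (0.03) and without PNXM657 (0.21). Macrophage markers were lower in 17 of 18 (-0.41, adjusted p = 0.00521, and adjusted p = 0.662 with an estimated correlation; -0.78 under quantile normalisation), with the mannose receptor Mrc1 at -0.91 ± 0.29 and the monocyte chemokine receptor Ccr2 at -0.79 ± 0.29, but -0.05 and not called without PNXM649 and -0.82 without PNXM657. Smooth muscle and pericyte markers were higher in 8 of 9 (0.51, adjusted p = 0.0239, and adjusted p = 0.635 with an estimated correlation), with Vtn (1.13 ± 0.29) and Kcnj8 (0.73 ± 0.23) past 0.05 when adjusted over the list alone. The pericyte call was lost under quantile normalisation (0.46) and without PNXM649 (0.46) or PNXM645 (0.50). Lymphocyte markers were lower in 12 of 14 (-1.06, adjusted p = 0.00929, and adjusted p = 0.648 with an estimated correlation), but not called without PNXM657 (-0.61), and the T cell gene Cd3g was -2.24 ± 0.84, or -0.96 without it. Neutrophil markers were higher in 14 of 16 (1.499, adjusted p = 0.0420, and adjusted p = 0.763 with an estimated correlation). The neutrophil call was lost with a pseudocount of 0.1 (1.53), under quantile normalisation (1.14) and without PNXM657 (1.01), PNXM661 (1.08), PNXM647 (0.63) or PNXM648 (0.84), and 2.33 without PNXM645. Dissociation genes were lower in 12 of 17 (-0.29, adjusted p = 0.0115, and adjusted p = 0.528 with an estimated correlation), with Nr4a1 at -1.13 ± 0.27 and Fos at -1.63 ± 0.47. When adjusted over the list alone, 5 were lower and 1 was higher. That call was lost without PNXM649 (-0.30). Nr4a1 was called over all genes without PNXM649 (-1.42) or PNXM645 (-1.27). The stress response list did not pass (0.14, adjusted p = 0.120, 0.05 without PNXM657, 0.04 without PNXM647 and -0.00137 under quantile normalisation), although Trib3 and Atf5 (1.22 ± 0.28) passed when adjusted over the list alone, and Atf5 was called over all genes without PNXM645 (1.45).

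The fourth comparison asked how knockout cardiomyocytes respond to isoproterenol. Mitochondrially encoded transcripts were lower here, with mt-Nd5 at -1.32 ± 0.41, mt-Nd6 at -1.30 ± 0.40, mt-Nd4 at -1.27 ± 0.40 and mt-Cytb at -1.10 ± 0.37. In all, 12 of 13 were lower (median -0.88, adjusted p = 5.38e-07, and adjusted p = 0.486 with an estimated correlation; -0.02 and not called under quantile normalisation, which equalises values at the top ranks), 6 when adjusted over the list alone and 0 over all genes. Among the smallest p-values, higher values were seen for Cox4i2 (1.10 ± 0.21), a cytochrome c oxidase isoform regulated by oxygen, the calcitonin receptor partner Ramp3 (1.05 ± 0.20), Higd1b (0.90 ± 0.23, or 0.52 without PNXM664), Dok4 (0.75 ± 0.19) and Eepd1 (0.61 ± 0.14). Lower values were seen for the leukocyte signalling genes Pik3cd (-0.83 ± 0.20), Map4k1 (-0.99 ± 0.25) and Dapp1 (-0.64 ± 0.16), the acid-sensing receptor Gpr65 (-0.70 ± 0.18) and the glutamine transporter Slc1a5 (-1.01 ± 0.26). Limma called 0 of 11919 genes (807 at an unadjusted p under 0.05; voom called 0), and 1 gene without PNXM663. Panx1 differed by -0.38 ± 0.16 (1.04 against 1.67 FPKM).

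Lymphocyte markers were lower in 14 of 14 in the knockout response (median -1.28, adjusted p = 2.32e-07, and adjusted p = 0.217 with an estimated correlation; -1.93 with a pseudocount of 0.1), with granzyme A, Gzma, at -1.09 ± 0.44. Macrophage markers were lower in 18 of 18 (-0.44, adjusted p = 0.000398, and adjusted p = 0.486 with an estimated correlation), with Ccr2 at -0.90 ± 0.29, but not called without PNXM664 (-0.24). Erythroid transcripts were lower in 9 of 9 (-1.45, adjusted p = 0.00112, and adjusted p = 0.486 with an estimated correlation; -0.92 under quantile normalisation and -2.20 without PNXM658), with the globin gene Hba-a2 at -1.97 ± 0.82. This erythroid call was lost without PNXM664 (-0.77). Recruitment signals were lower in 12 of 14 (-0.27, adjusted p = 0.0320, and adjusted p = 0.486 with an estimated correlation; -0.44 without PNXM658), with the leukocyte integrin Itgb2 at -1.08 ± 0.47. The recruitment call was lost without PNXM664 (-0.08) or PNXM654 (-0.23). Extracellular matrix genes were lower in 21 of 24 (-0.28, adjusted p = 0.00388, and adjusted p = 0.547 with an estimated correlation; -0.43 without PNXM658), with osteopontin, Spp1, at -0.82 ± 0.28. The matrix call was lost without PNXM664 (-0.08) or PNXM654 (-0.17). Endothelial markers were higher in 14 of 14 (0.36, adjusted p = 0.000294, and adjusted p = 0.486 with an estimated correlation; 0.23 without PNXM656, and 0.10 and not called under quantile normalisation), with Tie1 at 0.58 ± 0.21. Pericyte markers were higher in 8 of 9 (0.41, adjusted p = 0.0119, and adjusted p = 0.486 with an estimated correlation), with Kcnj8 at 0.70 ± 0.23, and their call was lost under quantile normalisation (0.27) and without PNXM656 (0.36). Fibroblast markers were called lower (-0.38, against 0.45 in the wild-type response), a call lost without PNXM664 (-0.17). Fatty acid oxidation (0.56), the tricarboxylic acid cycle (0.58), contraction genes (0.64) and glycolysis (0.45) were called higher, and clock genes lower (-0.42). Neutrophil markers had a median of 0.72 and were not called, against 1.499 in the wild-type response. The glycolysis call was lost without PNXM654 (0.20) and the clock call without PNXM663 (-0.19). With an estimated correlation 0 lists were called in this response. The nuclear respiratory chain was higher in 40 of 40 (0.80, adjusted p = 5.24e-10, and adjusted p = 0.486 with an estimated correlation; 0.41 under quantile normalisation and 0.45 without PNXM654). The hypertrophy programme was higher in 11 of 14 (0.30, adjusted p = 0.0467, and adjusted p = 0.486 with an estimated correlation), with Lmcd1 at 0.79 ± 0.27. Its median was 0.39 in the wild-type response, where it was not called. In the difference of the responses it was -0.11, so the programme was not particular to knockout cells. The hypertrophy call was lost under quantile normalisation (0.13) and without PNXM658 (0.09), PNXM664 (0.33), PNXM654 (0.11), PNXM655 (0.28) or PNXM646 (0.27), and the median was 0.46 without PNXM656.

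The fifth comparison tested whether the knockout effect differed between isoproterenol and saline. Over 11919 genes the knockout effects after saline and after isoproterenol correlated with r = 0.42, and genes are not independent replicates. At an unadjusted p under 0.01, 1 gene was higher in both (0.199 by chance) and 1 lower in both (0.0821 by chance). In opposite directions, 21 were higher after saline and lower after isoproterenol (0.553 by chance), and 0 the other way round. Mitochondrially encoded transcripts gave the clearest difference, with mt-Atp6 at -2.67 ± 0.49, mt-Nd2 at -2.55 ± 0.48, mt-Nd1 at -2.48 ± 0.46, mt-Co1 at -2.61 ± 0.50. Similar values were seen for mt-Cytb at -2.61 ± 0.52, mt-Co3 at -2.65 ± 0.52, mt-Co2 at -2.65 ± 0.57, mt-Nd4 at -2.64 ± 0.57 and mt-Atp8 at -2.27 ± 0.44. The list fell in 13 of 13 (median -2.61, adjusted p = 9.37e-41), and of all list calls in the 7 comparisons this was the only one that held with an estimated correlation (adjusted p = 0.0283). Of its members 12 passed when adjusted over the list alone and 0 over all genes, and quantile normalisation put the median at 0.00 because it equalises values at the top ranks. The mitochondrial share of reads differed by -33.1 percentage points (permutation of genotype within treatment, p = 0.00163, adjusted p = 0.0348), with all 3 saline knockout libraries above and all 4 isoproterenol knockout libraries below the wild-type libraries of the same treatment. The number of assigned reads differed in the same test, by 7.92 M (permutation p = 0.00327, adjusted p = 0.0348), and was lower in all 3 saline knockout libraries than in any saline wild-type library. Limma called 0 of 11919 genes (smallest adjusted p = 0.190, 294 at an unadjusted p under 0.05; voom called 0), 2 without PNXM657 and 1 without PNXM645. Panx1 differed by -0.06 ± 0.22, and by 0.09, 0.03 and 0.00 without PNXM661, PNXM664 and PNXM647, -0.21 without PNXM657, -0.17 without PNXM663, -0.12 without PNXM645, -0.10 without PNXM655 and -0.04 without PNXM646.

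**Figure D2:**
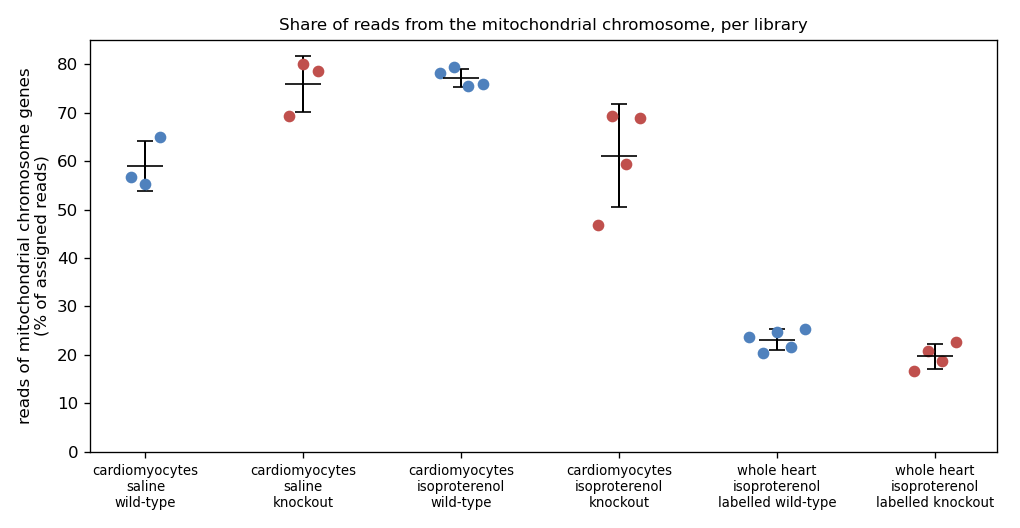
Percent of assigned reads on the mitochondrial chromosome (vertical axis) for each library (points) with group mean and SD. Saline knockout cardiomyocytes averaged 75.9% against 59.0% in wild-type cells, isoproterenol knockout cardiomyocytes 61.1% against 77.2%, and hearts labelled knockout 19.7% against 23.2%.

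Among other lists in the difference of the knockout effects, fibroblast markers were lower in 14 of 14 (median -0.76, adjusted p = 2.07e-12, and adjusted p = 0.263 with an estimated correlation), with Tcf21 (-1.08 ± 0.31) and Gsn (-1.30 ± 0.39) past 0.05 when adjusted over the list alone and Dpt at -0.94 ± 0.38. Dissociation genes were higher in 14 of 17 (0.39, adjusted p = 1.53e-05, and adjusted p = 0.0547 with an estimated correlation; 0.62 under quantile normalisation and 0.25 without PNXM649), with Egr1 (1.15 ± 0.31) past 0.05 when adjusted over the list alone and Nr4a1 at 0.92 ± 0.38. The stress response was lower in 14 of 17 (-0.19, adjusted p = 0.00225, and adjusted p = 0.574 with an estimated correlation; -0.28 with a pseudocount of 0.1, -0.30 without PNXM649 and -0.11 without PNXM647), with Trib3 (-0.91 ± 0.20) past 0.05 when adjusted over the list alone, Ddit3 at -0.53 ± 0.19 and Atf5 at -0.97 ± 0.40. Endothelial markers were lower in 12 of 14 (-0.38, adjusted p = 0.000682, and adjusted p = 0.574 with an estimated correlation; -0.25 without PNXM644), with Eng at -0.93 ± 0.33. The endothelial call was lost under quantile normalisation (-0.20) and without PNXM649 (-0.25) or PNXM654 (-0.21). Erythroid transcripts were lower in 9 of 9 (-1.70, adjusted p = 9.88e-05, and adjusted p = 0.574 with an estimated correlation; -1.02 without PNXM664), with Hba-a2 at -2.35 ± 1.16, and the call was lost under quantile normalisation (-0.73). Clock genes were lower in 11 of 14 (-0.77, adjusted p = 0.00826, and adjusted p = 0.574 with an estimated correlation), with Arntl, of the activating arm, at 1.59 ± 0.55 and Tef and Nr1d1, which it drives, at -1.34 ± 0.49 and -1.21 ± 0.48. The clock call was lost without PNXM663 (-0.36), PNXM654 (-0.68) or PNXM645 (-0.55). Neutrophil markers did not pass (-0.66, adjusted p = 0.0968) and were 0.10 without PNXM647, -0.38 without PNXM657, -0.36 without PNXM661, -0.24 without PNXM654 and -0.26 without PNXM648. They were called without PNXM658 (-0.80), PNXM649 (-1.32), PNXM644 (-1.22), PNXM645 (-1.498) or PNXM656 (-1.27).

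The 84 genes called in the wild-type response were followed in knockout cells, which share no library with them. Because they were chosen on their wild-type change, smaller values elsewhere are in part a result of that choice. Of the 67 genes outside the mitochondrial chromosome that rose, 64 had the same sign in knockout cells, with a median of 0.46 against 1.06. The 67 include the unprocessed pseudogenes Gm28438 (1.80) and Gm13341 (1.52). Whether their reads came from mitochondrial transcripts was not tested. Of the 11 mitochondrial-chromosome genes 0 had the same sign, with a median of -0.71 against 1.71. All 6 genes that fell had the same sign, with -0.56 against -1.06. Over 11919 genes the responses correlated across genes with r = 0.69, and genes are not independent replicates. At an unadjusted p under 0.01, 43 genes were higher in both responses (2.35 by chance) and 37 lower in both (2.67 by chance).

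The sixth comparison asked what differs in whole hearts after isoproterenol between hearts labelled knockout and hearts labelled wild-type, with the reservation that Panx1 was higher in the former. Macrophage markers were higher in hearts labelled knockout in 13 of 13 (median 0.33, adjusted p = 1.38e-13, and adjusted p = 0.233 with an estimated correlation), 5 when adjusted over the list alone and 0 over all genes. Mrc1 was 3.56 ± 0.33 FPKM (SD, n = 4) against 2.30 ± 0.43 FPKM (SD, n = 5), a difference of 0.48 ± 0.11. The lysozyme gene Lyz2 differed by 0.52 ± 0.18, Cd68 by 0.39 ± 0.14 and Adgre1 by 0.27 ± 0.09. The metalloproteinase inhibitor Timp1 was higher by 1.00 ± 0.24 and Itgb2 by 0.41 ± 0.10 (0.66 with a pseudocount of 0.1), both past 0.05 when adjusted over their lists alone. Genes of fatty acid oxidation were lower in 29 of 30, with Etfdh at -0.40 ± 0.12, Decr1 at -0.42 ± 0.13 and Hadha at -0.37 ± 0.13. Limma called 0 of 10189 genes (smallest adjusted p = 0.254, 652 at an unadjusted p under 0.05; voom called 0). The smallest p-values included higher Fam46b (0.83 ± 0.12), the secreted neurotrophic factor Ndnf (1.07 ± 0.17, and called at 1.204 with an adjusted p = 0.0155 by limma without PNXM227, where 2 genes were called), Efhd2 (0.73 ± 0.14), the glutamate transporter Slc17a7 (1.41 ± 0.28), Klhdc7a (0.73 ± 0.15) and the p53 target Phlda3 (1.01 ± 0.21). Lower values were seen for the potassium channel subunit Kcnv2 (-0.54 ± 0.09), Ogdhl, related to oxoglutarate dehydrogenase (-0.88 ± 0.15), the calcium channel gene Cacna1s (-0.47 ± 0.09) and Tmem82 (-0.73 ± 0.14). Myh6 differed by -0.31 ± 0.22, and by -0.16 without PNXM199 and -0.19 without PNXM241.

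Across the lists in hearts labelled knockout, fatty acid oxidation had a median of -0.32 (adjusted p = 6.18e-09, and adjusted p = 0.371 with an estimated correlation). The tricarboxylic acid cycle, with Sucla2 at -0.42 ± 0.14, was lower in 24 of 24 (-0.25, adjusted p = 2.97e-07, and adjusted p = 0.371 with an estimated correlation; -0.15 under quantile normalisation and -0.16 without PNXM239). Mitochondrially encoded proteins, with mt-Atp6 at -0.70 ± 0.23, were lower in 12 of 13 (-0.39, adjusted p = 9.74e-05, and adjusted p = 0.371 with an estimated correlation; and -0.02 and not called under quantile normalisation, which equalises values at the top ranks). Nuclear respiratory chain genes, with Ndufs1 at -0.33 ± 0.11, were lower in 40 of 40 (-0.21, adjusted p = 1.23e-05, and adjusted p = 0.537 with an estimated correlation; -0.10 under quantile normalisation, -0.09 without PNXM241 and -0.08 and not called without PNXM239). Contraction genes were lower in 18 of 21 (-0.29, adjusted p = 0.000856, and adjusted p = 0.371 with an estimated correlation), with Trdn at -0.34 ± 0.10, Hrc at -0.45 ± 0.15 and phospholamban, Pln, at -0.46 ± 0.16. This contraction call was lost under quantile normalisation (-0.09) and without PNXM199 (-0.16). Matrix genes were higher in 24 of 24 (0.25, adjusted p = 1.38e-07, and adjusted p = 0.371 with an estimated correlation; 0.12 without PNXM239 and 0.14 without PNXM230). Fibroblast markers were higher in 13 of 14 (0.22, adjusted p = 0.000229, and adjusted p = 0.371 with an estimated correlation; 0.14 without PNXM230 and 0.06 and not called without PNXM199). The hypertrophy programme was higher in 9 of 14 (0.25, adjusted p = 0.000280, and adjusted p = 0.371 with an estimated correlation), with Uchl1 (0.85 ± 0.19) past 0.05 when adjusted over the list alone and Nppa, atrial natriuretic peptide, at 1.84 ± 0.74. Scores of atrial markers ranged from 0.86 to 7.38 in hearts labelled knockout and from 0.93 to 4.91 in hearts labelled wild-type. The hypertrophy call was lost without PNXM229 (median -0.0051, adjusted p = 0.356), and the median was 0.47 without PNXM199 and 0.58 without PNXM239. Recruitment signals were higher in 8 of 9 (0.29, adjusted p = 0.000102, and adjusted p = 0.233 with an estimated correlation; 0.14 without PNXM199). Dissociation genes were higher in 14 of 17 (0.17, adjusted p = 0.000102, and adjusted p = 0.273 with an estimated correlation; 0.34 with a pseudocount of 0.1, 0.33 without PNXM238 and 0.28 without PNXM242), with Junb at 0.43 ± 0.16. The stress response was higher in 10 of 13 (0.12, adjusted p = 0.000747, and adjusted p = 0.233 with an estimated correlation; 0.08 without PNXM199, 0.18 without PNXM239 and 0.19 without PNXM241), with Chac1 at 0.48 ± 0.13. Endothelial markers did not pass (-0.13, adjusted p = 0.0887) but were called without PNXM199 (-0.20) or PNXM230 (-0.12). Adipocyte markers did not pass either (0.96, adjusted p = 0.0631, 5 of 6 higher), with 0.10 without PNXM199, 1.49 without PNXM238 and 0.24 without PNXM239, and were called without PNXM229 (1.64) or PNXM242 (1.62). Neutrophil markers had 0 genes above the expression filter in whole hearts.

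**Figure D3:**
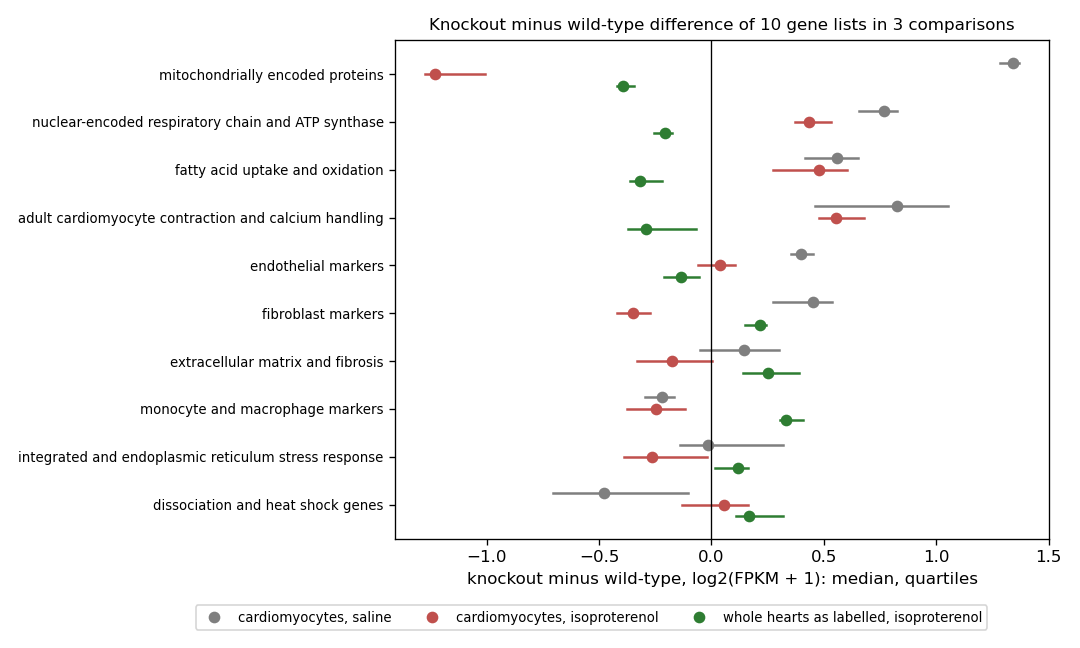
Median (point) and quartiles (line) over the members of 10 gene lists, as knockout minus wild-type difference of log2(FPKM + 1), in saline cardiomyocytes, isoproterenol cardiomyocytes and whole hearts as labelled. The 10 lists were chosen after the results were seen. The mitochondrially encoded list lies at 1.34, -1.23 and -0.39 in the 3 comparisons, and at 0.00, 0.00 and -0.02 under quantile normalisation.

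The last comparison tested whether the isoproterenol knockout effect differed between whole hearts as labelled and cardiomyocytes. Panx1 itself differed, by 0.748 FPKM (permutation of genotype within tissue, p = 0.00034, adjusted p = 0.0109), higher in hearts labelled knockout and lower in knockout cardiomyocytes, and by 0.54 ± 0.14 on the log2 scale (1.05 with a pseudocount of 0.1). Lymphocyte and neutrophil markers are not compared between the tissues, since 1 and 0 of them passed the filter in whole hearts. The stress response was higher in 15 of 17 (0.46, adjusted p = 3.68e-07, and adjusted p = 0.154 with an estimated correlation). Of its members 6 passed 0.05 when adjusted over the list alone, including the serine and folate enzymes Phgdh (1.58 ± 0.39), Psat1 (0.64 ± 0.17) and Mthfd2 (0.85 ± 0.25) and the asparagine synthetase Asns (0.79 ± 0.20). With a pseudocount of 0.1 these were 2.57, 1.29, 1.55 and 1.43. Macrophage markers were higher in 18 of 18 (0.53, adjusted p = 3.55e-08, and adjusted p = 0.250 with an estimated correlation), with Cd68 at 0.77 ± 0.22 and Lyz2 at 1.34 ± 0.46. Recruitment signals were higher in 12 of 13 (0.48, adjusted p = 7.83e-05, and adjusted p = 0.250 with an estimated correlation), with Itgb2 at 1.49 ± 0.43 and Ccl5 at 0.98 ± 0.27. Fatty acid oxidation was lower in 29 of 30 (-0.75, adjusted p = 3.68e-07, and adjusted p = 0.457 with an estimated correlation), with Acot2 at -0.92 ± 0.35 and Etfdh at -0.87 ± 0.39. Contraction genes were lower in 21 of 21 (-0.79, adjusted p = 4.36e-05, and adjusted p = 0.457 with an estimated correlation; -0.51 without PNXM654), with Pln at -1.16 ± 0.50. Mitochondrially encoded proteins, with mt-Atp8 at 0.96 ± 0.34, were higher in 13 of 13 (0.83, adjusted p = 1.74e-06, and adjusted p = 0.422 with an estimated correlation; 0.00 under quantile normalisation, which equalises values at the top ranks). Matrix genes, with Timp1 at 1.12 ± 0.39, were higher in 21 of 24 (0.42, adjusted p = 9.02e-05, and adjusted p = 0.457 with an estimated correlation). Limma called 0 of 11386 genes (smallest adjusted p = 0.231, 1240 at an unadjusted p under 0.05; voom called 0), 7 without PNXM645, 4 without PNXM644 and 4 without PNXM656. The smallest p-values included Aldh18a1 (0.67 ± 0.12, called at 0.73 without PNXM645), Akap7 (-0.61 ± 0.12), Ptk2b (1.42 ± 0.28), Efhd2 (1.09 ± 0.22) and Smco4 (-1.22 ± 0.25). They also included the T cell kinase gene Lck (0.89 ± 0.18, called at 1.03 without PNXM645, and 1.79 with a pseudocount of 0.1), the antigen presentation gene H2-DMa (1.08 ± 0.23), Lsp1 (1.13 ± 0.24) and Ly6d (2.13 ± 0.47, called at 2.46 without PNXM656). No gene was called in both tissues, since limma called 0 in each (739 and 652 at an unadjusted p under 0.05; voom 0 in each). At an unadjusted p under 0.01, 0 genes were higher in both (0.188 by chance) and 0 lower in both (0.472 by chance). In opposite directions, 3 were lower in knockout cardiomyocytes and higher in hearts labelled knockout (0.364 by chance, Fisher's exact p = 0.00568) and 1 the other way round (0.244 by chance). That Fisher p rests on 3 genes and is not adjusted over the 4 combinations of direction. It treats genes as independent replicates, which they are not. The knockout effects correlated across 9850 genes with r = -0.30.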

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

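The tests of scaling and cardiomyocyte share for the first pattern, of endothelial RNA and scaling for the next, and of cardiomyocyte share for the last were chosen after the result was seen, and the tests of depth, of PNXM657 and of atrial tissue before it was run.

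Mitochondrially encoded proteins differed between the knockout effects under isoproterenol and saline by -2.61, and the mitochondrial percent of reads by -33.1. The scaling between libraries could produce the difference of -2.61, but the mitochondrial percent is a share of unscaled reads and does not depend on it. Its exact permutation p = 0.00163 is that of the flagged difference itself and no separate test. The contraction score differed by -0.22 ± 0.63 (SE) against -2.44 ± 0.50 (SE) for the mitochondrially encoded score, a gap of -2.22 ± 0.96 (SE). The gap was above 2 SE for each of 4 nuclear cardiomyocyte lists. This would argue against different shares of cardiomyocytes as the whole cause only if a share moved both scores alike. Wild-type isoproterenol preparations, set against whole hearts labelled wild-type, were higher in mitochondrially encoded genes (3.57) but lower in contraction genes (-1.74). The test therefore cannot decide the question. The rule for this test was revised more than once after its values were seen, an earlier version left the question open, and an exact permutation of the gap to the nuclear respiratory chain alone gave p = 0.0669, two-sided. Depth may also matter, since the difference was -17.4 ± 8.2 (SE) with assigned reads as a covariate against -33.1 ± 7.4 (SE) without, which leaves it open.

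Endothelial genes were higher in wild-type cardiomyocytes after isoproterenol. More RNA of endothelial cells in the preparations could explain this, but no test here separates it from regulation: the 12 fixed markers that were not called had a median of 0.75, which the list median of 0.78 already implies. The lymphocyte-rich library PNXM657 might have produced it, but the median was 0.76 without it. The scaling could have set the level of the change. The endothelial median was 0.43 after rescaling without mitochondrially encoded genes and -0.36 without the scaling. It is 1 factor per library, but on log2(FPKM + 1) it moves genes of low FPKM less than others. The median of all genes was also negative without the scaling, at -0.78. The sign change by itself is therefore no evidence that it raised endothelial genes in particular. Their excess over the median of all genes was 0.74, and 0.65 after rescaling, 0.42 without the scaling and 0.34 under quantile normalisation, the last too small for the rule, so this test also stays open, and its rule, like those of the other scaling test and of endothelial RNA, was set or revised after values were seen.

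Macrophage markers were higher in hearts labelled knockout. A lower share of cardiomyocytes could raise all other cells alike, but the macrophage score minus the endothelial score also differed (exact permutation p = 0.00794, two-sided). Atrial tissue could carry more macrophages, but the score differed by 0.28 ± 0.10 (SE) with the atrial score as a covariate and by 0.29 ± 0.09 (SE) without it. Fibroblast markers (0.22) and matrix genes (0.25) were higher too, and contraction (-0.29) and fatty acid oxidation genes (-0.32) lower, as a lower share would give. Endothelial (-0.13) and smooth muscle and pericyte markers (-0.27) were lower. The comparison with 1 other cell type, at an unadjusted p, therefore cannot exclude a lower share of cardiomyocytes. The atrial score did not account for the pattern, and Panx1 ran against the labels in these hearts.

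Other differences of the knockout effect between isoproterenol and saline cardiomyocytes were -0.76 in fibroblast markers, -0.38 in endothelial markers, -1.70 in erythroid transcripts, 0.39 in dissociation genes, -0.19 in the stress response and -0.77 in clock genes. Recruitment signals differed by -0.28 (camera adjusted p = 0.0240, and adjusted p = 0.632 with an estimated correlation), a call lost without PNXM657 (-0.15), PNXM664 (-0.16), PNXM654 (-0.19), PNXM647 (-0.19), PNXM645 (-0.30) or PNXM655 (-0.27). Matrix genes differed by -0.29 (adjusted p = 0.00278), a call lost without PNXM657 (-0.13), PNXM664 (-0.17) or PNXM654 (-0.18), and ribosomal protein genes by -0.32 (adjusted p = 2.14e-05), a call lost without PNXM661 (-0.15), with -0.52 without PNXM649 and -0.48 without PNXM645. Both had an adjusted p = 0.714 with an estimated correlation, and quantile normalisation ended the recruitment (-0.10), matrix (-0.18) and ribosomal (-0.03) calls.

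Between whole hearts as labelled and cardiomyocytes the knockout effect differed by -0.75 in fatty acid oxidation, -0.75 in the tricarboxylic acid cycle (-0.45 without PNXM654), -0.79 in contraction genes (-0.51 without PNXM654), 0.42 in matrix genes and 1.36 in erythroid transcripts (0.87 without PNXM647, 0.80 without PNXM199), each with an adjusted p = 0.457 with an estimated correlation. It differed by -0.65 in the nuclear respiratory chain (adjusted p = 0.560 with an estimated correlation; -0.31, -1.03 and -0.996 without PNXM654, PNXM656 and PNXM648). Smooth muscle and pericyte markers differed by -0.46 (adjusted p = 0.0167, and adjusted p = 0.457 with an estimated correlation), a call lost without PNXM656 (-0.38), PNXM648 (-0.48), PNXM238 (-0.30) or PNXM240 (-0.34). Ribosomal protein genes differed by 0.10 (adjusted p = 0.0381, and adjusted p = 0.693 with an estimated correlation), a call lost without PNXM644 (0.0955), PNXM647 (0.101), PNXM656 (0.0486), PNXM646 (0.0326), PNXM648 (0.0232), PNXM199 (0.0253), PNXM238 (0.0651) or PNXM240 (0.0717), with 0.19 to 0.23 without PNXM654, PNXM645, PNXM655, PNXM239 or PNXM241. Mitochondrially encoded proteins differed by 0.83 and fibroblast markers by 0.56 (both adjusted p = 0.422 with an estimated correlation), recruitment signals by 0.48 and macrophage markers by 0.53 (both 0.250), the stress response by 0.46 (0.154), and Panx1 by 0.748 FPKM. The values of 1.45 in neutrophil and 1.18 in lymphocyte markers rest on the cardiomyocytes, since 0 and 1 of these markers passed the filter in whole hearts, and are no comparison of the tissues.

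Among 120 sets of values, 10 had a library far from the others where chance gives about 1 in 20, that is 6. PNXM648 stood apart in the nuclear respiratory chain score at 7.35 (others 5.90 to 6.01), the hypertrophy score at 3.35 (2.86 to 2.89) and the dissociation score at 3.03 (3.28 to 3.33). PNXM241 did so in the tricarboxylic acid score at 7.39 (7.01 to 7.10), the respiratory chain score at 8.17 (7.51 to 7.70) and the ribosomal score at 6.77 (6.20 to 6.36). PNXM229 had a hypertrophy score of 5.38 (4.32 to 4.34), PNXM238 a dissociation score of 3.32 (2.81 to 2.95), PNXM199 an interferon score of 1.77 (1.53 to 1.56) and PNXM230 a Panx2 value of 0.615 FPKM (0.290 to 0.382).

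Libraries were also regrouped at random. In the wild-type response 84 genes were called and 1 of 35 splits, the real one, reached that count (highest other 12). At an unadjusted p under 0.05 it had 2896 genes, and 2 of 35 splits had as many, the highest other 3373. Where 0 genes were called every split is as large by construction (10 of 10 in saline cardiomyocytes, 35 of 35 in isoproterenol cardiomyocytes, 35 of 35 in the knockout response, and 100 of 100 in each of the others), so the counts at an unadjusted p under 0.05 are given as well. In saline cardiomyocytes 6 of 10 splits had as many as the real 421 (highest count of called genes in another split 13), and these are too few splits for a share under 0.05. As many were found in 10 of 35 splits in isoproterenol cardiomyocytes (real 739, another split with 2191 called genes), 10 of 35 in the knockout response (real 807, 0 called), 54 of 100 in the difference of the responses (real 294, 8 called), 24 of 100 in whole hearts (real 652, 67 called) and 19 of 100 between tissues (real 1240, 3243 called), so chance is not excluded in these. The splits with 2191 and 3243 called genes show that groupings other than the real one can differ in many genes. What the libraries grouped in them share was not tested.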

How the results depend on the processing

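Voom, unscaled FPKM, covariates and left-out groups of libraries were chosen after the result was seen. No paired analysis was possible because the columns carry no replicate number.

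In the wild-type response limma called 84 genes. This became 129 with a filter of FPKM 5, 2 under quantile normalisation, 0 after rescaling without mitochondrially encoded genes, 1262 with array weights (773 higher, 489 lower), 2 with only the groups compared (0 higher, 2 lower), 1089 with all libraries in 1 fit (547 higher, 542 lower), 7564 with unscaled FPKM (14 higher, 7550 lower), 1 without PNXM654, PNXM655 and PNXM648, and 18 without PNXM657 and PNXM658, with 0 to 222 when 1 library was left out. In the saline comparison 0 became 10 without a filter, 5978 with unscaled FPKM and 12 without PNXM657 and PNXM658 (leave-one-out 0 to 10). Unscaled FPKM gave 5083 in isoproterenol cardiomyocytes, 9739 in the difference of the responses and 1703 between tissues, all from 0. All libraries in 1 fit gave 1 in the knockout response (leave-one-out 0 to 1), 31 in the difference (0 to 2) and 1 in whole hearts (0 to 2). Array weights gave 16 in the difference, 6 in whole hearts and 170 between tissues, with convergence warnings in 5 fits, and no filter gave 6 between tissues (leave-one-out 0 to 7).

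Quantile normalisation turned ribosomal protein genes to -0.0733 in the saline comparison, -0.11 in the wild-type response and -0.13 in the knockout response, and the stress response to -0.00137 in the wild-type response. The mitochondrially encoded list goes to about 0 because equal ranks receive equal values.

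Leaving out 1 library gave, in the saline comparison, -0.01 to 0.16 for pannexins, connexins and purinergic receptors (-0.0138 without PNXM664), -0.57 to 0.12 for macrophage markers, -0.86 to 0.45 for lymphocyte markers and -1.09 to 0.0549 for proliferation. It gave -0.95 to 0.0480 for proliferation in the knockout response, and in the difference of the responses -0.60 to 0.11 for the nuclear respiratory chain (0.06 without PNXM648), -1.50 to 0.10 for neutrophil markers and -0.21 to 0.0883 for Panx1 (0.03 without PNXM664, 0.00 without PNXM647). In hearts labelled knockout the hypertrophy programme ranged from -0.0051 to 0.58. Leaving out a library of the smallest group raises the number of genes tested, because the filter follows that group.

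Beyond what construction shows, the cause was not tested. Median-of-ratios scaling moved nothing because the deposited values already carry such a scaling, so it is no test. Of the 101 called list results, 100 weakened with an estimated correlation and 1 held, and with fry 96 weakened and 5 held. Lists given as not called stayed so in both. Cardiomyocyte libraries held 5.30 to 11.8 M reads outside the mitochondrial chromosome on group average, which limits what low-expressed genes can show.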

Other observations

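The genes Gpihbp1, Sox18, Nos3 and Ramp2, and the comparison of preparations with whole hearts were chosen after the result was seen. Further endothelial genes called in the wild-type response were Gpihbp1, which anchors lipoprotein lipase in capillaries (1.46 ± 0.23, from 18.3 ± 0.73 to 53.0 ± 12.1 FPKM, SD, n = 3 and 4), Sox18 (1.48 ± 0.29), Nos3, the endothelial nitric oxide synthase (1.09 ± 0.19), and Ramp2 (1.14 ± 0.19). In the knockout response, the purinergic and junction genes Adora2a (0.79 ± 0.23), P2ry12 (-0.60 ± 0.19) and Gjc1 (0.40 ± 0.14) passed when adjusted over their list alone, although the list did not pass (0.13, adjusted p = 0.604). P2ry1 was lower in hearts labelled knockout (-0.49 ± 0.12) and differed between the tissues (-0.71 ± 0.22), as did the connexin gene Gja1 (-0.88 ± 0.29), each past 0.05 when adjusted over the list alone.

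The cardiomyocyte preparations held transcripts of many other cells. Wild-type isoproterenol preparations exceeded whole hearts labelled wild-type by a median of 6.71 in erythroid, 3.86 in neutrophil, 3.57 in mitochondrially encoded, 1.71 in lymphocyte, 1.49 in endothelial, 1.48 in macrophage and 1.36 in fibroblast genes, and were lower by a median of -1.74 in contraction, -1.76 in fatty acid oxidation and -1.97 in tricarboxylic acid cycle genes (tissue and preparation differ together, and no test was made).

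Lower immune transcripts in knockout cardiomyocytes could reflect fewer leukocytes in the preparation or in the heart. Medians after saline were also negative, at -0.59 for neutrophil, -0.22 for macrophage and -0.49 for lymphocyte markers (the last not called). They rested on single libraries, with -0.08 (neutrophil) and 0.12 (macrophage) without PNXM649 and 0.45 (lymphocyte) without PNXM657. Whether the lower values are particular to isoproterenol therefore stays open. Whole hearts do not settle whether leukocytes were fewer, since 0 neutrophil markers and 1 lymphocyte marker passed the filter there. The macrophage score was higher in hearts labelled knockout by 0.28 with the atrial score as a covariate. Since Panx1 ran against the labels in whole hearts, the sign of every whole-heart difference might be the reverse of the genotype effect.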
